A study of Arabidopsis thaliana with 9 samples.

How the data were processed

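Polyadenylated RNA of whole Arabidopsis thaliana seedlings of 14 days was sequenced in 9 libraries, from 3 biological replicates each of wild type (accession Col-0), the smd1b mutant (allele smd1b-3) and the prp39a mutant (allele prp39a-3), per the labels. The library kit was a stranded mRNA kit, per the labels' protocols. The labels call the replicates independent biological ones, so the p-values measure the spread between such samples.

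The deposited values are TPM, a transcript's share of all transcripts scaled to a fixed total, with 1 value per transcript isoform and library, and the table's column names carry the name of the quantifier kallisto; its version and the transcript annotation are not given in the sources used here. Per the submitters' processing notes, the build was TAIR10 and the tools Trimmomatic, TopHat2, featureCounts and DESeq2 were used, without roles or versions; none of these is stated to have made the TPM table. Each column of the deposited TPM table sums to 1000000, so the number of reads behind a value is unknown, no count test was run, and no counting interval can be given. A value of 0 in such a table can be a low number of reads or an estimate that assigned none, so a gene at 0 is described as listed at 0. Kallisto-type estimates divide reads shared between similar transcripts, so values of near-identical gene copies and of similar isoforms of 1 gene are uncertain. The table holds 82190 isoforms of 34212 genes. It has 15 columns of values, of which 9 could be matched to the samples through their names, and the other 6 were not used. The columns named col, smdb1 and prp39 with a number were taken as the wild-type, smd1b and prp39a libraries of that number.

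Isoform TPM were summed per gene identifier. Genes with a mean of at least 1 TPM over the 9 libraries were tested (20585 genes, of which 20369 are named in the annotation supplied for assembly TAIR10.1) on log2(TPM + 0.5). For isoforms, the tested value was log2 of (isoform TPM + 0.5) over (TPM of the gene's other isoforms + 0.5), for isoforms with a mean share of 0.05 to 0.95 of the gene's TPM in genes with a mean of at least 1 TPM (21990 isoforms of 8587 genes). Because of the pseudocount, fold changes of low genes are understated. An isoform is measured against the other isoforms of its gene, so a fall of 1 raises others. Counts of isoforms higher and lower therefore tend to balance, and 1 event can be counted more than once. Linear models were fitted to all 9 libraries with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), and 3 contrasts were taken: smd1b against wild type, prp39a against wild type, and prp39a against smd1b. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each contrast at 0.05. Because both mutants were compared with the same 3 wild-type libraries, overlaps were set beside 100 simulated data sets with no effect, drawn from the within-group residuals, and beside the overlap of independent lists.

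The groups, tests, alternatives and gene lists and the naming rule were fixed before the data were examined. The 15 lists cover U1 snRNP and Sm core proteins, SR splicing factors, RNA decay and quality control, small RNA silencing machinery, trans-acting siRNA precursors and targets, DNA methylation and transcriptional silencing, flowering time, circadian clock, salicylic acid and immune response, heat shock response, cold, drought and abscisic acid response, photosynthesis, anthocyanin synthesis, and markers of root and floral organs. Lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, and with fry; p-values were adjusted over the 15 lists of a contrast. The named genes are the mutated genes and their paralogs; the 8 largest rises and 8 largest falls per mutant with an adjusted p under 0.05, all 3 mutant values outside the 3 wild-type values and a mean of at least 5 TPM in the higher group; up to 4 members per list with the smallest adjusted p; the 6 isoforms with the smallest adjusted p in genes of at least 5 TPM; and the 5 largest changes each way between the mutants.

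The procedure was tested on simulated data with 200 changed features. Noise was drawn independently for each feature, from variances fitted to the real data. It lacks the variation that genes share within groups, so the rates below may not hold for the real libraries. For smd1b against wild type, with 20585 genes, 86% of genes changed by 1 on the log2 scale and 99% of those changed by 2 were recovered, and 7.04% of the calls were false. For prp39a against wild type the shares were 94% and 97%, with 4.5% false calls. For prp39a against smd1b they were 97% and 99%, with 3.92% false calls. For isoforms (21990 tested), a change of 1 was recovered in 6%, 7% and 12% of cases in the 3 contrasts in the same order, and a change of 2 in 81%, 84% and 84%, so isoform counts miss most small changes.

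Alternatives were pseudocounts of 0.1 and 1, median-ratio size factors, other filters on TPM and isoform share, an arcsine transform of the share, a prior without trend, a fit with only the 6 libraries compared, the replicate number as a block, and each library left out in turn. An isoform filter requiring 1 TPM in each genotype was added after the data were seen. A planned test of the share of intron-retaining isoforms was not run: only 17004 of the isoform names (20.7%) occur in the supplied annotation, and 157 of the 13266 tested genes with more than 1 isoform have all isoforms there, so the structure of most isoforms is not known here. Gene coordinates come from the TAIR10.1 annotation; the TPM table itself has none. Within groups, library correlations on the log2 scale were 0.972 to 0.99, and between groups 0.957 to 0.986.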

Results

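Seedlings of 3 Arabidopsis genotypes were compared by RNA sequencing, with 3 libraries each. SmD1b is a core protein of the spliceosomal small nuclear ribonucleoproteins (snRNPs), and PRP39a is a protein of the U1 snRNP, the particle that recognises 5′ splice sites. The study's title concerns a joint role of both proteins in the silencing of transgenes. The comparisons here describe how the endogenous transcripts of each mutant line differed from wild type. Between 7.2% and 10.2% of a library's TPM came from its 10 most abundant genes. The number of reads per library is unknown, because TPM keep no depth.

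The mutated genes were low in their own mutant and not in the other. SMD1B (AT4G02840, chromosome 4, 1264518 to 1266486 in TAIR10.1) had 52.3 ± 1.81 TPM (SD, n = 3) in wild type and 54.2 ± 4.68 TPM in prp39a. In smd1b it was listed at 0 in 2 libraries and at 0.138 TPM in the other. PRP39A (AT1G04080, chromosome 1, 1051312 to 1056827) fell from 51.2 ± 3.46 TPM in wild type to 5.50 ± 0.074 TPM in prp39a (log2 fold change −3.11 ± 0.064 SE, limma adjusted p = 2.41e-08) and stood at 52.6 ± 1.21 TPM in smd1b. The paralog SMD1A had 15.03 ± 2.41 TPM in wild type and 21.4 ± 2.35 TPM in smd1b, which did not pass the test (adjusted p = 0.108). The paralog PRP39B had 8.58 ± 0.341 TPM in wild type and 8.01 ± 0.66 TPM in prp39a (adjusted p = 0.498).

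**Figure D1:**
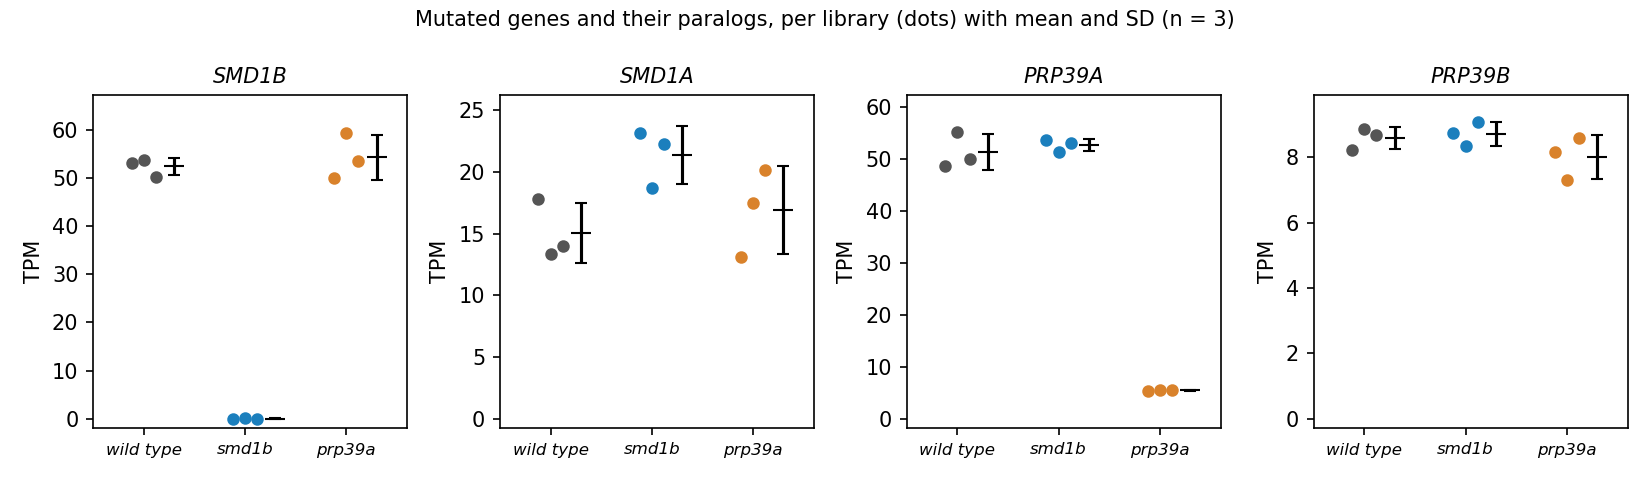
TPM of SMD1B, SMD1A, PRP39A and PRP39B in the 9 libraries (dots), with the mean and SD of each genotype (n = 3). SMD1B is at or near 0 in the smd1b libraries, and PRP39A is at 5.50 TPM in prp39a.

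The comparison of smd1b with wild type asked which transcripts differed in the smd1b line. The neighbours of SMD1B on chromosome 4 were nearly silent in smd1b together with it. Of the 6 adjacent genes from AT4G02800 to AT4G02850, FAF1 was listed at 0 in all smd1b libraries and the others stood at 0.1% to 0.9% of wild type. AT4G02800, AT4G02820 (wild type 7.33 ± 0.568 TPM), AT4G02830 (6.15 ± 0.943 TPM) and AT4G02850 (9.33 ± 2.06 TPM) were among the 8 largest falls. The flanking genes EMB3129 and AT4G02860 stood at 104% and 95.4% of wild type, and in prp39a the silent genes were expressed, for example AT4G02800 at 7.60 ± 0.378 TPM. On chromosome 3, the adjacent genes AT3G55900 (5.69 ± 1.37 TPM in wild type) and AT3G55910 (5.37 ± 0.782 TPM) were listed at 0 in all smd1b libraries. The next gene, AT3G55920, which encodes a cyclophilin-like protein, stood at 30.4% of wild type.

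**Figure D2:**
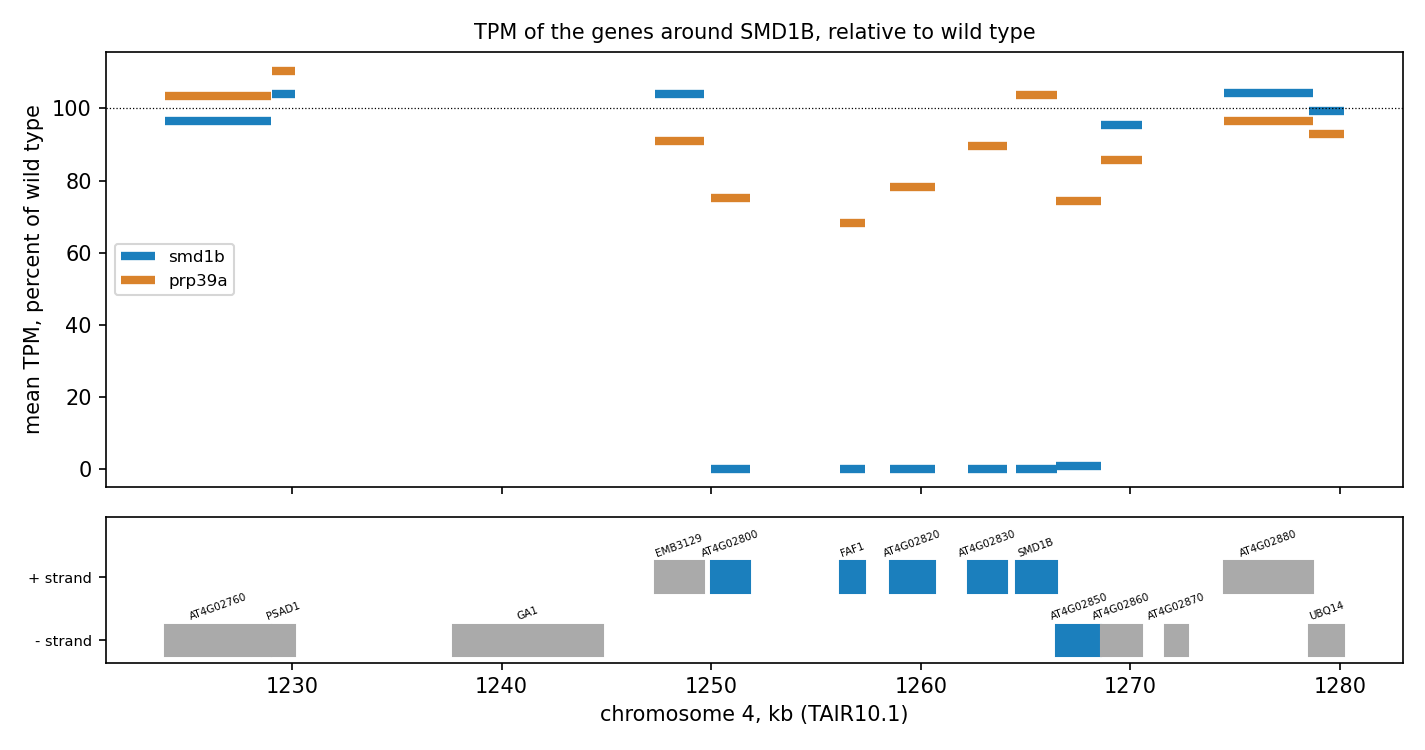
Mean TPM of each gene in smd1b and prp39a as a percentage of the wild-type mean (vertical axis), by position on chromosome 4 in kb of TAIR10.1 (horizontal axis), for genes with at least 0.5 TPM in wild type; boxes show gene spans by strand, with the 6 silent genes in blue. The 6 genes from AT4G02800 to AT4G02850 lie between 0% and 0.9% in smd1b, and the flanking genes at 104% and 95.4%.

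Elsewhere in the genome, the flowering repressor FLC (AT5G10140, chromosome 5) fell in smd1b from 7.65 ± 0.784 TPM to 0.333 ± 0.155 TPM (log2 fold change −3.30 ± 0.175 SE, adjusted p = 1.62e-05). The uncharacterised gene AT1G75945 fell from 32.5 ± 2.78 TPM to 0.409 ± 0.235 TPM. The largest rises were mostly of transcripts nearly absent in wild type. The noncoding RNA AT2G01422 rose from 0.0211 ± 0.0366 to 11.3 ± 1.15 TPM, and AT2G11773, AT2G40955 and AT2G05914 rose from 0.537, 0.101 and 0.0751 TPM to 17.7, 6.46 and 6.02 TPM. AT4G16805 and AT3G28899, listed at 0 in all wild-type libraries, rose to 7.38 ± 4.47 and 5.13 ± 1.45 TPM. SADHU3-2, a retroelement-derived pseudogene, rose from 3.21 ± 0.372 to 40.5 ± 2.05 TPM (log2 fold change 3.47 ± 0.131 SE, adjusted p = 1.64e-06). PR1, a marker of salicylic acid defence, rose from 66.5 ± 41.1 to 645 ± 343 TPM (adjusted p = 0.0342). In all, 1365 of 20585 genes changed, 735 higher and 630 lower, of which 214 changed at least 2-fold. With size factors 1531 changed, 749 higher and 782 lower, so the direction of the majority turned. The count was 542, 610 and 517 without wild-type replicates 1, 2 and 3, and 546 and 376 without smd1b replicates 2 and 3. The call for PR1 was lost without each of these same 5 libraries (adjusted p from 0.0524 to 0.126), and that for AT4G16805 without any 1 of the 3 wild-type and 3 smd1b libraries (0.0751 to 0.0935). Both were also lost with no TPM filter (0.0623 and 0.0602).

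Among the flowering genes, 4 of 22 tested rose in smd1b (GI, SVP, FUL and MAF5) and 2 fell (FLC and AGL24), the same numbers when adjusted over the list alone; 3 rose with size factors. MAF5, a relative of FLC, rose from 0.969 ± 0.105 to 2.39 ± 0.45 TPM, and AGL24, a promoter of flowering, fell from 9.13 ± 1.27 to 5.35 ± 1.22 TPM. Of 18 clock genes, the evening genes GI (34.6 ± 1.56 to 49.0 ± 1.25 TPM) and PRR3 (22.2 ± 1.56 to 32.7 ± 2.89 TPM) rose and the morning gene CCA1 fell (7.78 ± 0.835 to 3.62 ± 0.125 TPM); adjusted over the list alone, 3 rose and 2 fell. Of 27 small RNA silencing genes, the RNA-dependent RNA polymerase RDR1 rose from 8.48 ± 0.959 to 13 ± 0.884 TPM and the Argonaute AGO2 from 6.41 ± 0.635 to 8.74 ± 0.89 TPM, and 2 also rose when adjusted over the list alone. Of 22 immune genes, PR1 and SAG101 rose and the transcription factor WRKY40 fell (22.7 ± 6.25 to 11.5 ± 0.799 TPM); adjusted over the list alone, 4 rose and 1 fell. The anthocyanin regulators PAP1 (2.24 ± 0.287 to 5.61 ± 1.44 TPM) and PAP2 (2.6 ± 0.988 to 5.77 ± 0.946 TPM) rose, 2 of 8 tested by either adjustment. Of 10 DNA methylation and silencing genes, the demethylase ROS1 fell from 16.9 ± 0.827 to 11.2 ± 0.765 TPM and QQS, an orphan gene under epigenetic control, from 18.0 ± 0.963 to 8.30 ± 2.03 TPM, 2 of 10 by either adjustment.

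Of 24 U1 snRNP and Sm core genes, U1-70K fell in smd1b from 63.1 ± 1.00 to 49.2 ± 2.22 TPM (adjusted p = 0.0141) besides SMD1B itself, 2 genes by either adjustment. Of 8 heat shock genes, HSP70-4 fell (14.3 ± 2.42 to 10.3 ± 0.575 TPM), and 2 fell when adjusted over the list alone. None of 20 SR splicing factor genes, 27 RNA decay genes, 9 trans-acting siRNA genes, 14 cold, drought and abscisic acid genes, 21 photosynthesis genes, 8 root markers or the 1 floral marker tested passed limma's test over all genes. At an unadjusted p under 0.05 there were 5, 1, 2, 0, 3, 0 and 0 genes of these lists. Adjusted over the list alone, 2 SR genes fell and no other gene of these lists passed, and with size factors 1 SR gene fell over all genes. No list as a whole passed camera in smd1b against wild type, where 4 of 15 lists had an unadjusted p under 0.05. By limma's fry, 0 lists moved on balance in 1 direction and 9 held genes changed in either direction, among them the U1 snRNP and Sm core list, which holds SMD1B itself. The smallest camera adjusted p was 0.0568, for the anthocyanin, immune and heat shock lists, and the smallest with an estimated correlation was 0.745. Without wild-type replicate 2, photosynthesis (adjusted p = 0.0105) and heat shock (0.0107) passed as lower and anthocyanin (0.0107) and immune (0.0465) as higher. Without wild-type replicate 3, immune (0.00478) passed as higher and heat shock (0.0287) as lower, and immune (0.00983) and anthocyanin (0.0189) passed as higher without smd1b replicates 1 and 3.

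Many calls for the named list genes of smd1b depended on single libraries or on a setting. Those for AGO2 and HSP70-4 were each lost without any 1 of 8 libraries (AGO2 passed without smd1b replicate 1, and HSP70-4 without wild-type replicate 3), with adjusted p from 0.051 to 0.163 and from 0.0547 to 0.155. Without wild-type replicate 1, AGL24, SAG101 and PAP1 were also lost (0.0798 to 0.101), and without wild-type replicate 2, GI, WRKY40, SAG101 and PAP1 (0.0512 to 0.088). Without wild-type replicate 3, U1-70K, GI, AGL24, WRKY40, PAP1, PAP2 and ROS1 were lost (0.05 to 0.0966). Without smd1b replicate 1, AGL24, WRKY40 and PAP1 were lost (0.0569 to 0.0656), and without smd1b replicate 2, U1-70K, GI, AGL24, WRKY40, SAG101, PAP1 and PAP2 (0.0545 to 0.101). Without smd1b replicate 3, U1-70K, MAF5, GI, WRKY40, SAG101, PRR3, PAP2 and ROS1 were lost (0.056 to 0.12). With no TPM filter, AGO2, AGL24, WRKY40, HSP70-4, PAP1 and PAP2 were lost (0.0501 to 0.0698), in a fit of the 6 libraries alone AGO2, AGL24, HSP70-4 and PAP2 (0.0512 to 0.0709), and with a prior without trend HSP70-4 (0.0545). FLC, QQS, CCA1 and RDR1 passed in each of these fits.

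The isoform comparison asked where the mix of transcripts from a gene changed. In smd1b, the isoform AT1G28060.1 of the gene of pre-mRNA-splicing factor 3 rose from 62.2% ± 0.888 to 91.1% ± 0.117 of the gene's TPM (SD, n = 3; adjusted p = 0.000767), and the isoform named AT1G28060_JC1 fell from 37.5% ± 0.643 to 8.79% ± 0.0781. The isoform AT1G32230_P2 of RCD1, a regulator of stress responses, fell from 29.0% ± 1.77 to 7.04% ± 0.615 (adjusted p = 0.0013). AT4G10970_P1 fell from 17.1% ± 4.77 to 0.000267% ± 0.000463. At AT3G55920, whose total TPM stood at 30.4% of wild type and whose span (20743443 to 20745153 on chromosome 3) overlaps that of the silent gene AT3G55910 (20742676 to 20743479), the isoform AT3G55920_ID17 was listed at 0 in wild type and made up 100% in smd1b, while AT3G55920_P1 went from 67.8% ± 3.89 to a listed 0. Altogether 478 of 21990 isoforms changed their share, 238 higher and 240 lower, in 346 of 8587 genes (4.03%), and 49 of these genes also changed in total TPM. Isoforms that mirror each other, such as AT1G28060.1 and AT1G28060_JC1, are both counted. The median change was 13.9 percentage points, and 111 isoforms changed by more than 20 points. The count fell to between 98 and 172 when any 1 of the 6 libraries of this comparison was left out (131, 145 and 107 without wild-type replicates 1, 2 and 3, and 98, 172 and 171 without smd1b replicates 1, 2 and 3), to 303 and 284 without prp39a replicates 1 and 3, and to 106 in a fit of the 6 libraries alone.

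The comparison of prp39a with wild type asked which transcripts differed in the prp39a line. FLC rose from 7.65 ± 0.784 to 25.5 ± 5.66 TPM (log2 fold change 1.66 ± 0.175 SE, adjusted p = 0.00268), and QQS from 18.0 ± 0.963 to 92.5 ± 5.36 TPM (2.33 ± 0.151 SE, adjusted p = 0.000186). The largest rise was of the uncharacterised gene AT3G29633 (chromosome 3, 11452509 to 11453528), from 0.302 ± 0.0361 to 21.4 ± 2.2 TPM. The transcription factor genes AT4G05170 and ARF20 rose from 1.84 ± 0.609 to 15 ± 4.06 TPM and from 1.81 ± 0.288 to 10.5 ± 1.61 TPM, and the receptor kinase gene SRF4 rose from 4.23 ± 0.157 to 15.4 ± 3.16 TPM. NOGC1 and CRH1 rose from 1.39 ± 0.115 to 6.45 ± 0.345 TPM and from 1.43 ± 0.571 to 5.04 ± 0.549 TPM. AT5G05200, which encodes a protein kinase family member, fell from 125 ± 1.85 to 15.9 ± 0.643 TPM (−2.93 ± 0.053 SE, adjusted p = 1.47e-08). AT1G75945 fell to 0.428 ± 0.135 TPM, and the cupin gene AT5G39150 fell from 9.85 ± 3.96 to 0.641 ± 0.342 TPM. The glucosyltransferase gene DOGT1 fell from 6.09 ± 1.07 to 0.123 ± 0.213 TPM, AT1G13820 from 31.7 ± 4.1 to 7.68 ± 0.949 TPM, and AT4G21870 from 28.1 ± 8.38 to 7.84 ± 2.84 TPM. The gene of the small nucleolar RNA U60.2F fell from 11.6 ± 4.45 to 1.01 ± 0.882 TPM. It spans only 13075563 to 13075635 on chromosome 4, and the libraries were of polyadenylated RNA. Whether its values measure the small RNA itself is therefore not known. In all, 850 of 20585 genes changed, 357 higher and 493 lower, and 83 changed at least 2-fold. With size factors 995 changed, 614 higher and 381 lower; the median gene had a log2 fold change of −0.07 without them. The count was 361, 218 and 408 without wild-type replicates 1, 2 and 3, 273 and 437 without prp39a replicates 1 and 2, 489 without smd1b replicate 3, and 413 in a fit of the 6 libraries alone. The call for AT4G21870 was lost without wild-type replicate 1 or 2 or prp39a replicate 1 or 2 (adjusted p up to 0.103), that for U60.2F without any 1 wild-type library (up to 0.0854), and that for CRH1 without wild-type replicate 2 (0.0516). With no TPM filter U60.2F and AT4G21870 were lost (0.0516 and 0.0548), and with a pseudocount of 0.1 U60.2F (0.0528).

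Among 22 flowering genes, FLC and its relatives MAF1 (43.7 ± 2.76 to 73.0 ± 3.81 TPM) and MAF3 (23.4 ± 0.736 to 35.4 ± 1.78 TPM) rose in prp39a, as did SPL3 (19.7 ± 2.2 to 37.1 ± 6.55 TPM), and FLK fell; adjusted over the list alone, 5 rose and 6 fell, and with size factors 5 rose and 0 fell. Of 20 SR splicing factor genes, RS31 (46.5 ± 2.46 to 64.8 ± 1.5 TPM) and RS40 (102 ± 7.75 to 128 ± 6.28 TPM) rose and RS41 fell (81.2 ± 2.01 to 65.2 ± 3.47 TPM), by either adjustment; 4 rose and 1 fell with size factors. The SR list was higher relative to the other genes by camera (adjusted p = 0.0225, and 0.805 with an estimated correlation). Its own shift was small, with a median log2 fold change of 0.024 and 11 of 20 members above wild type. The median of all tested genes was −0.071. Of 8 heat shock genes, HSP70-4 (14.3 ± 2.42 to 8.19 ± 0.365 TPM), HSP90.1 (6.21 ± 0.841 to 3.91 ± 0.504 TPM) and HSP17.8 (2.07 ± 0.816 to 0.651 ± 0.0776 TPM) fell, 4 when adjusted over the list alone, and the list was lower (adjusted p = 0.0225; adjusted p = 0.805 with an estimated correlation). Of 27 small RNA silencing genes, the Argonaute AGO1 fell from 98.2 ± 8.77 to 75.5 ± 5.43 TPM and the chromatin remodeller CLSY1 from 4.36 ± 0.0864 to 2.56 ± 0.309 TPM, 2 by either adjustment; with size factors 1 also rose. Of 22 immune genes, WRKY40 (22.7 ± 6.25 to 9.51 ± 1.45 TPM) and WRKY33 (72.9 ± 14.4 to 44.8 ± 3.29 TPM) fell, 3 when adjusted over the list alone. Single libraries or a setting ended several of these calls. Without wild-type replicate 1, RS40, RS41, SPL3, HSP90.1 and HSP17.8 were lost (adjusted p from 0.0839 to 0.0934), and without wild-type replicate 2, CLSY1, AGO1, RS40, RS41, SPL3, WRKY40, WRKY33 and HSP90.1 (0.0633 to 0.116). Without wild-type replicate 3, AGO1, RS41, WRKY33 and HSP17.8 were lost (0.0667 to 0.0786). Without prp39a replicate 1, CLSY1, AGO1, RS40, RS41, SPL3, WRKY33, HSP90.1 and HSP17.8 were lost (0.0583 to 0.117). Without prp39a replicate 2 the same genes but CLSY1 were lost (0.0728 to 0.0937), and without prp39a replicate 3, AGO1, WRKY33 and HSP17.8 (0.0542 to 0.0599). AGO1 and RS40 were also lost without smd1b replicate 2 (0.052 and 0.0517), and AGO1, RS40, RS41, WRKY33, HSP90.1 and HSP17.8 without smd1b replicate 3 (0.0515 to 0.0615). In a fit of the 6 libraries alone the same 6 genes were lost (0.0638 to 0.0828), with a prior without trend AGO1 and RS40 (0.0507 and 0.0522), and with no TPM filter HSP90.1 (0.0515).

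The cold, drought and abscisic acid list was higher as a whole in prp39a by camera (adjusted p = 3.26e-06; adjusted p = 0.805 with an estimated correlation), with all 14 tested members above wild type and a median log2 fold change of 0.66, but none of them passed limma's test by either adjustment; 9 had an unadjusted p under 0.05. COR15B, a chloroplast cold protein gene, had 328 ± 155 TPM in wild type and 714 ± 154 TPM in prp39a (adjusted p = 0.125). These genes also varied between libraries of the same genotype: on the leading axis of within-group variation, which held 42.7% of it, this list had a median scaled loading of 1.77 and the root markers −2.96, and prp39a replicates 2 and 3 lay farthest out, at 32.1 and −30.5. The photosynthesis list was higher by camera (adjusted p = 0.0225; adjusted p = 0.956 with an estimated correlation) at a median of 0.10, while the member that passed, the small Rubisco subunit gene RBCS1B, fell from 216 ± 40.7 to 132 ± 8.07 TPM; with size factors the list did not pass (adjusted p = 0.0962). Of 10 DNA methylation and silencing genes 1 rose (QQS; 2 adjusted over the list alone, and 2 with size factors), and of 24 U1 snRNP and Sm core genes 1 fell (PRP39A, by either adjustment; with size factors 1 also rose). None of 18 clock, 27 RNA decay, 8 anthocyanin and 9 trans-acting siRNA genes, 8 root markers or the 1 floral marker passed over all genes in limma, with 5, 5, 2, 4, 1 and 0 at an unadjusted p under 0.05. Adjusted over the list alone, 2 trans-acting siRNA genes rose and 2 fell, and 0 genes of the other lists passed; with size factors 1 trans-acting siRNA gene rose over all genes. By fry, the heat shock list moved on balance in 1 direction (adjusted p = 0.0132), and 9 lists held genes changed in either direction. The U1 snRNP and Sm core list also passed fry in 1 direction (adjusted p = 0.0132), but it holds the mutated gene PRP39A, the 1 member that passed, and was not tested by fry without it, so nothing is read from this. The other lists called by camera did not pass fry in 1 direction (cold, drought and abscisic acid 0.395, SR 0.273, photosynthesis 0.696). The photosynthesis call was lost without wild-type replicate 2, prp39a replicate 1 or prp39a replicate 2 (adjusted p = 0.841, 0.261 and 0.159), the heat shock call without prp39a replicate 1 or 3 (0.0579 and 0.0652), and the SR call without prp39a replicate 2 (0.157). The call for RBCS1B was lost without wild-type replicate 1 or 2, smd1b replicate 3 or prp39a replicate 1 or 2 (0.0518 to 0.0937), in a fit of the 6 libraries alone (0.0504) and with no TPM filter (0.056).

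Isoform shares changed at more genes in prp39a than total TPM did. The isoform AT1G76520_P1 of an auxin efflux carrier family gene fell from 18.7% ± 0.996 to 0.000109% ± 0.000188 of the gene's TPM (adjusted p = 6.37e-06), and AT1G13770_P1 of RUS3 fell from 60.04% ± 6.14 to 0.376% ± 0.652. AT4G24740_P2, from the gene of the LAMMER-type kinase AFC2, AT2G24690_P2, from a B3 transcription factor gene, and AT5G02810_c2, from the clock gene PRR7, fell from 14.7% ± 1.64, 38.1% ± 4.07 and 8.90% ± 1.13 in wild type to means of 1.75e-09%, 1.89e-10% and 5.18e-08% in prp39a. The main isoform AT5G51820_P1 of the phosphoglucomutase gene PGM fell from 98.6% ± 0.334 to 86.9% ± 1.22. Altogether 2332 of 21990 isoforms changed, 1207 higher and 1125 lower, in 1426 of 8587 genes (16.61%), of which 174 changed in total TPM. The median change was 14.6 percentage points, and 691 isoforms changed by more than 20 points. The count was 1525, 1460 and 1548 without wild-type replicates 1, 2 and 3 and 1387 and 1499 without prp39a replicates 1 and 3.

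**Figure D3:**
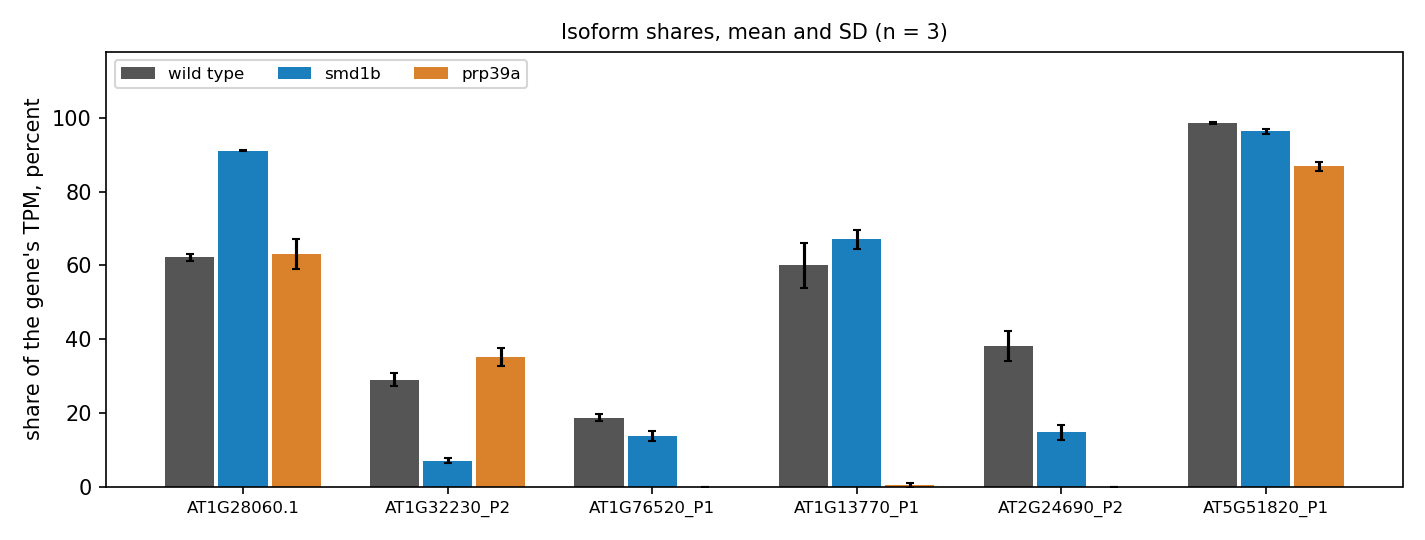
Mean share of the gene's TPM (percent, vertical axis) of 6 named isoforms in wild type, smd1b and prp39a; bars are means and error bars SD (n = 3). AT1G28060.1 rises from 62.2% to 91.1% in smd1b, and AT1G13770_P1 falls from 60.04% to 0.376% in prp39a.

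The direct comparison of prp39a with smd1b tested where the mutants differed from each other. FLC was higher in prp39a by 4.96 ± 0.175 SE on the log2 scale (adjusted p = 6.84e-07), and AT3G29633, SMD1B and its neighbour AT4G02800, and AT3G55900 completed the 5 largest differences in that direction. PR1 was lower in prp39a (21.8 ± 21.0 TPM, against 645 ± 343 TPM in smd1b, adjusted p = 0.0033), as were SADHU3-2 (0.729 ± 0.211 TPM against 40.5 ± 2.05 TPM), DOGT1 (0.123 ± 0.213 TPM against 15.4 ± 7.51 TPM), the noncoding RNA AT4G04223 (6.11 ± 1.09 TPM against 119 ± 1.80 TPM) and AT2G11773, listed at 0 in all prp39a libraries against 17.7 ± 10.5 TPM. Of 22 immune genes 7 were lower in prp39a, among them ICS1, PAD3 and PAD4 besides PR1, 11 when adjusted over the list alone, and the list was lower (camera adjusted p = 0.00623; adjusted p = 0.823 with an estimated correlation). Of 20 SR genes 6 were higher and 1 lower, by either adjustment (list adjusted p = 0.00552; adjusted p = 0.823 with an estimated correlation); with size factors 7 were higher and 0 lower. Of 14 cold, drought and abscisic acid genes, COR15A, COR15B, NCED3 and LTI30 were higher, 5 when adjusted over the list alone (list adjusted p = 7.19e-05; adjusted p = 0.823 with an estimated correlation), and 3 were higher with size factors. This list also loaded on the axis of variation within genotypes, at 1.77. Of 21 photosynthesis genes, 3 antenna genes (LHCB1.1, LHCB1.3 and LHCB2.1) were higher and the Rubisco subunit genes RBCS1B and RBCS2B lower, 4 and 2 when adjusted over the list alone and 2 and 1 with size factors (list adjusted p = 0.00552; adjusted p = 0.823 with an estimated correlation).

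Of 27 small RNA silencing genes, RDR6 was higher in prp39a than in smd1b and HYL1, RDR1, AGO1, NERD and CLSY1 were lower, the same numbers when adjusted over the list alone. The list was lower (camera adjusted p = 0.0297; adjusted p = 0.823 with an estimated correlation). With size factors 2 genes were lower and the list did not pass (adjusted p = 0.0539). Of 22 flowering genes 4 were higher and 8 lower (4 and 10 adjusted over the list alone, and 4 and 4 with size factors), of 18 clock genes 3 and 4 (4 and 6 adjusted over the list alone, and 4 and 4 with size factors), and of 27 RNA decay genes 0 and 4 (0 and 2 adjusted over the list alone, and 0 and 2 with size factors). Of 10 DNA methylation and silencing genes, ROS1, QQS and DRM2 were higher (3 adjusted over the list alone). Of 8 anthocyanin genes PAP1 and LDOX were lower (3 adjusted over the list alone, and 1 with size factors), of 8 heat shock genes HSP90.1, and of 8 root markers PYK10, each 1 by either adjustment. Of 9 trans-acting siRNA genes TAS1A was higher and ARF4 lower (3 and 2 adjusted over the list alone, and 2 and 1 with size factors). Of 24 U1 snRNP and Sm core genes U1-70K and SMD1B were higher and PRP39A, SME1 and PRP40C lower (2 and 5 adjusted over the list alone; 2 and 1 with size factors), and the 1 floral marker did not pass. These lists and those of flowering, clock and RNA decay did not pass camera (smallest adjusted p = 0.154). By fry, 2 lists moved on balance in 1 direction, SR and small RNA silencing (both adjusted p = 0.037), and 11 held genes changed in either direction, among them the U1 snRNP and Sm core list with both mutated genes. The cold, drought and abscisic acid (0.145), immune (0.061) and photosynthesis (0.34) lists did not pass fry in 1 direction. Over all genes, 4336 of 20585 differed, 1316 higher and 3020 lower in prp39a, and 338 differed at least 2-fold. With size factors the split changed to 2194 higher and 2027 lower of 4221. For isoform shares, 2978 of 21990 differed, 1520 higher and 1458 lower, in 1833 genes. The gene count was 2100 and 2728 without prp39a replicates 1 and 2 and 2565 and 2068 without smd1b replicates 1 and 3; the isoform count was 1848 and 1955 without prp39a replicates 1 and 2 and 1984 without smd1b replicate 1. The immune list did not pass without smd1b replicate 2 or prp39a replicate 3 (adjusted p = 0.0547 and 0.142), and the small RNA list without smd1b replicate 2, prp39a replicate 2 or prp39a replicate 3 (0.0659, 0.0875 and 0.0612).

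**Figure D4:**
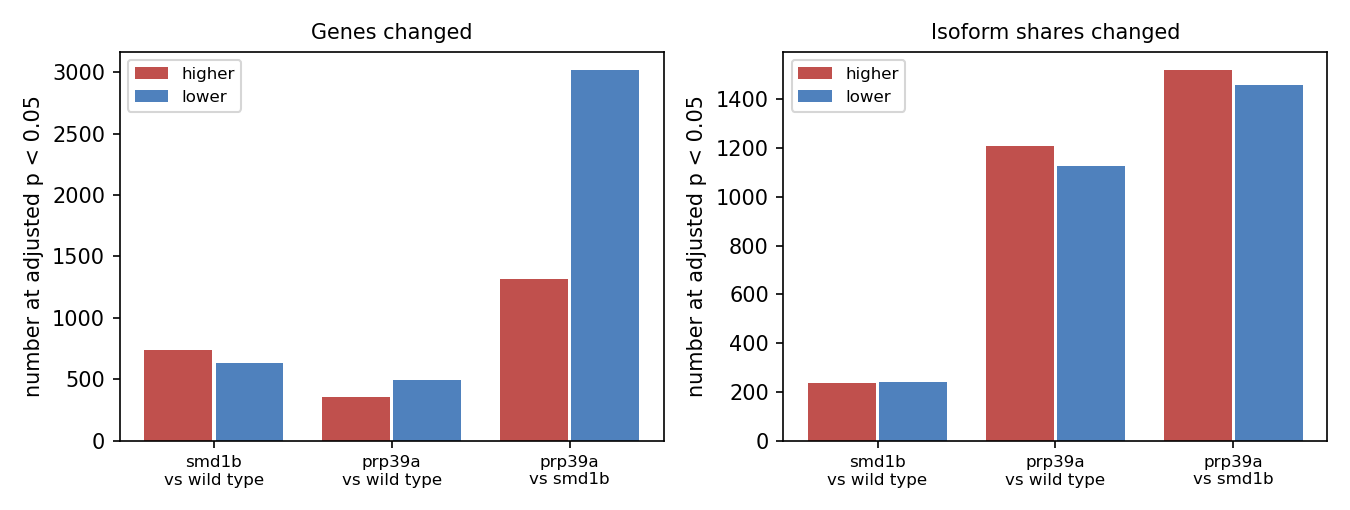
Number of genes (left) and isoform shares (right) with an adjusted p under 0.05 in each comparison, by direction (bars). The largest bar is the 3020 genes lower in prp39a than in smd1b.

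Genes changed against wild type in both mutants were also compared. AT1G75945 and AT5G39150 were low in both: AT1G75945 fell from 32.5 ± 2.78 TPM to 0.409 ± 0.235 TPM in smd1b and 0.428 ± 0.135 TPM in prp39a, and AT5G39150 from 9.85 ± 3.96 TPM to 0.539 ± 0.153 and 0.641 ± 0.342 TPM. A total of 56 genes were higher in both and 81 lower in both, where independent lists of these sizes would share 12.7 and 15.1. Another 27 were higher in smd1b and lower in prp39a, and 15 the reverse, FLC and QQS among them. No number for independent lists was computed for opposite directions, for genes or for isoforms. Nothing is therefore read from the counts of opposite changes. Over genes, which are not independent replicates, the fold changes of the mutants correlated at 0.26. Data sets simulated with no effect had a median of 0.58, with 95% of values from −0.554 to 0.929, so 0.26 lay within their spread. The covariance was 0.0254 against a simulated median of 0.0134, with 95% of simulated values from −0.011 to 0.0641. For isoforms, 77 were higher in both and 81 lower in both, against 13.1 and 12.3 for independent lists, and 9 and 11 changed in opposite directions. Isoforms of 1 gene mirror each other and are not independent entries. How far chance alone could exceed 13.1 and 12.3 is therefore not known. The isoform correlation was 0.31 (simulated 0.61, from −0.46 to 0.925) and the covariance 0.124 (simulated 0.0644, from −0.0392 to 0.234). The 100 simulated data sets gave 0 genes and 0 isoforms changed the same way in both, with a median of 0 calls in either mutant. The wild-type libraries could not be split into groups of at least 2, so part of the overlap may come from their use in both comparisons. The number of genes changed the same way in both, 137, was 62, 40 and 53 without wild-type replicates 1, 2 and 3, 70 and 49 without smd1b replicates 2 and 3, and 57 and 91 without prp39a replicates 1 and 2; the number of isoforms, 158, was 40, 43 and 34 without these wild-type replicates, 36, 54 and 69 without smd1b replicates 1, 2 and 3, and 85 and 71 without prp39a replicates 1 and 3.

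**Figure D5:**
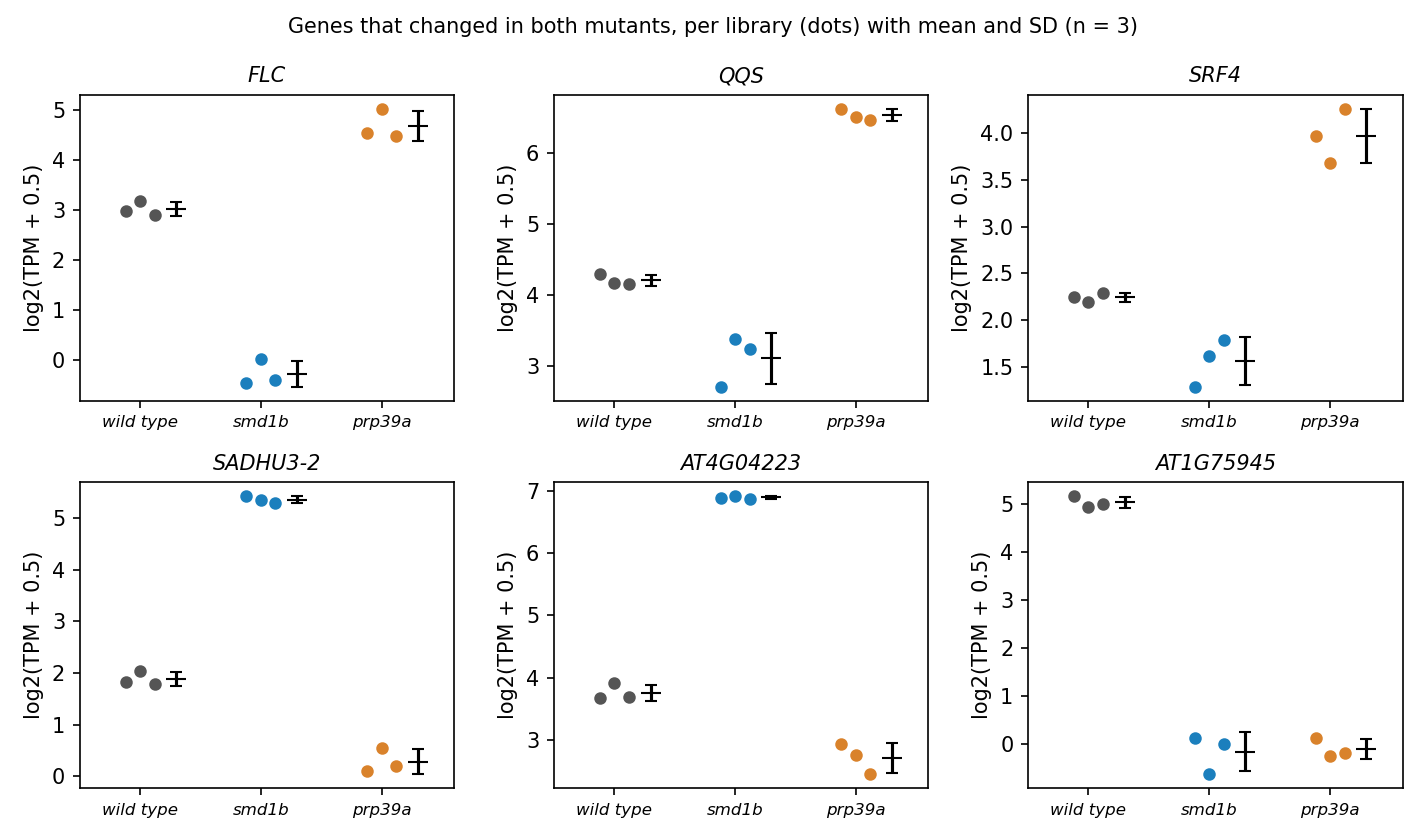
Values of log2(TPM + 0.5) per library (dots) with mean and SD (n = 3) for FLC, QQS, SRF4, SADHU3-2, AT4G04223 and AT1G75945. The first 5 lie on opposite sides of wild type in the mutants, and AT1G75945 is low in both.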

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

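Of the tests in this part, those of the run of neighbouring genes and of the genes flanking silent ones were chosen only after the result was seen. For both tests of scaling, the use of size factors was planned, and the bounds were set only after the result was seen.

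Libraries of a group of 3 were not tested for outlying values. By limma's tests against wild type, 27 genes were higher in smd1b and lower in prp39a, and 15 the reverse. These counts were not set beside those of independent lists. Of these genes, 5 are among those named by the rule fixed beforehand and are given here. As they were taken for opposite calls against wild type, a difference between the mutants was already fixed, so only its size is given. The log2 difference, prp39a minus smd1b, was 4.96 for FLC and 3.43 for QQS, both lower in smd1b and higher in prp39a. It was 2.41 for the receptor kinase gene SRF4, which had 2.48 TPM in smd1b, 4.23 TPM in wild type and 15.4 TPM in prp39a. For the pseudogene SADHU3-2 it was −5.07 and for the noncoding RNA AT4G04223 it was −4.19, both higher in smd1b and lower in prp39a than in wild type.

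In smd1b, genes near 0 TPM lay side by side. Among 16001 genes with at least 5 TPM in wild type, 9 stood under 5% of wild type in smd1b. Of these, 5 formed 1 run of neighbours that includes SMD1B itself, where 10000 random gene orders gave a run of at most 2. This argues against an effect of SmD1b on these genes wherever they lie on the chromosomes. Random orders treat neighbours as changing independently, which may not hold. Runs of 3 or more neighbours changed in 1 direction numbered 12 in smd1b, against at most 8 in random orders. These runs may include the one at SMD1B. A lesion of the DNA in the smd1b line, such as a deletion, is a candidate explanation: the genes flanking the SMD1B stretch kept at least 95.4% of their wild-type TPM, as a lesion with sharp ends would leave them, but local silencing would leave the same RNA values, so the 2 cannot be told apart without DNA reads. A lesion is as open on chromosome 3, where AT3G55900 and AT3G55910 were listed at 0 in smd1b and AT3G55890 and AT3G55940 stood at 131% and 112% of wild type; the isoform switch of AT3G55920, which overlaps AT3G55910, could then reflect a truncated gene rather than splicing. Changes elsewhere in smd1b may therefore follow from the loss of SmD1b or of a neighbour such as FAF1. They may also follow from the low genes on chromosome 3 or from another difference of this line. The design, with 1 allele, does not part these. The prp39a line was also represented by 1 allele. Beside PRP39A, AT1G04090, below the 1 TPM filter, stood at 0.412 TPM in wild type and 0.0375 TPM in prp39a. The nearby genes TOM22-I and IAA10 stood at 11.2 and 5.76 TPM in wild type and 11.2 and 5.59 TPM in prp39a.

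More genes differed between prp39a and smd1b (4336) than between either mutant and wild type (1365 and 850), and 3020 of them were lower in prp39a. With size factors 52% of the called genes were higher in prp39a, against 30.4% without. Size factors centre the median log2 fold change by construction (−0.081 without them, 0.006 with them). This pulls the share toward balance whatever the cause, so the test cannot decide whether TPM scaling accounts for part of the direction. TPM scaling does not account for the number, which was 4221 with size factors. Opposite effects of the mutations were tested by the covariance of their fold changes, 0.0254, against a median of 0.0134 in 100 data sets simulated with no effect. The bound set beforehand against opposite effects, a covariance above this median, was met, but 75 of the 100 simulated values lay at or below the observed one, so the difference of 0.012 was within the simulated spread and leaves this open, as does a biological difference between the genotypes.

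Some genes changed the same way in both mutants, 137 in number. Chance overlap of independent lists is argued against, since 81 genes were lower in both, where 15.1 were expected and the upper hypergeometric point was 23. Chance values of the shared wild-type libraries could still raise the number. The comparison with simulated data, which had been set to exclude this if 137 exceeded every simulated number, decides nothing, because the simulated sets had a median of 0 calls and so an overlap of 0. A shared effect of both mutations stays open beside it, and was not tested.

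Each comparison of 3 libraries with 3 allows 10 splits, which cannot give a share under 0.05. In each, 1 split, the real one, gave as many calls. The real counts of genes were 1365, 850 and 4336 for smd1b against wild type, prp39a against wild type and prp39a against smd1b, and the highest of the other splits 0, 0 and 1. For isoform shares the real counts were 478, 2332 and 2978, and the highest others 2, 1 and 3. Every other split mixes both genotypes within each group, so a real difference adds to its spread and lowers its count. The gap between the real and the other counts therefore decides nothing.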

How the results depend on the processing

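The isoform filter of 1 TPM in each genotype was chosen after the data were seen; the other settings were planned. No change of pseudocount, filter, transform or prior and no size factors moved the count of genes or isoforms by more than 1.5 times. In a fit of only the 2 groups compared, 413 genes changed in prp39a and 106 isoforms in smd1b, with fewer libraries behind the variance. With an estimated correlation, 0 lists passed in prp39a against wild type and 0 in prp39a against smd1b. With the replicate number as a replicate block, 832 and 343 genes changed in smd1b and prp39a, and 154 isoforms changed in smd1b. In both mutants, 54 genes and 41 isoforms changed the same way. No source used here states that the numbers pair the libraries. Of 9 libraries, 2 correlated best with a library of their own number, which gives no sign of pairing but cannot exclude it. Without pairing, this fit only spends degrees of freedom. In it, the smd1b calls for AT4G16805, WRKY40, SAG101 and HSP70-4 were lost (limma adjusted p from 0.0572 to 0.0858). So were the prp39a calls for AGO1, RS40, RS41, SPL3, WRKY33, HSP90.1 and HSP17.8 (0.0601 to 0.0894). Leaving out 1 library at a time gave 376 to 1422 genes in smd1b, 218 to 836 in prp39a and 2068 to 4443 between the mutants. Isoform counts ranged from 98 to 427, from 1387 to 2306 and from 1848 to 2733 in the same order. Overlaps ranged from 40 to 119 genes and from 34 to 107 isoforms, and lists passing from 0 to 4 in smd1b, from 2 to 5 in prp39a and from 3 to 5 between the mutants. Fold changes turned sign in 6 cases, none past the threshold. PRP39B in smd1b ranged from −0.01 to 0.05, with −0.011 without wild-type replicate 1 and −0.008 without smd1b replicate 3. SMD1B in prp39a ranged from −0.018, without prp39a replicate 2, to 0.103. CASP1 in smd1b ranged from -0.53 to 0.074, the latter without wild-type replicate 2. SEP3 in prp39a ranged from −0.232 to 0.108, with 0.044 without wild-type replicate 1 and 0.108 without prp39a replicate 2. Where no construction is named, the cause was not tested. Among named results past the threshold, genes kept direction and call in 1071 combinations with a setting and lost the call in 153. The gene tally includes the combinations of the isoform AT1G28060.1. The other named isoforms kept direction and call in 204 of 204. They were named for the smallest adjusted p, so this was likely beforehand. It does not speak for isoform calls in general, which fell to as few as 98 in smd1b. Over the estimated correlation and the leave-outs, lists kept their call in 70 and lost it in 20, and with size factors 2 more were lost, photosynthesis in prp39a against wild type (0.0962) and small RNA silencing between the mutants (0.0539). Among genes not past the threshold, 21 combinations passed. The intron-retention test was not run, nor were its other settings. The depth of the libraries is unknown, so what it limits cannot be stated.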

Other observations

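The isoforms described here and the tests of the U1 snRNP, trans-acting siRNA and pseudogene hypotheses were chosen only after the values were seen.

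Isoform values of 4 genes of the splicing lists follow. Over all genes tested, 4.03% changed an isoform share in smd1b and 16.61% in prp39a. Of 19 SR genes 1 changed in smd1b and 5 in prp39a (Fisher's exact test against the other genes, adjusted p = 1 and 0.654), so no gathering of changes in the SR list was detected. SR30, an SR protein gene, had its isoform AT1G09140_P2 at 67.1% of its TPM in wild type, 44.0% in smd1b (limma adjusted p = 0.0213) and 84.4% in prp39a (adjusted p = 0.00489), and the mutants differed from each other (adjusted p = 0.000209). U1-70K had its isoform AT3G50670_s2 at 25.4% in wild type, 6.69% in smd1b (adjusted p = 0.0119) and 4.45% in prp39a (adjusted p = 0.000685). In prp39a the RNA left from PRP39A itself was mixed differently. AT1G04080_P1 made up 54.9% in wild type and 4.89% in prp39a (limma adjusted p = 0.000361), and AT1G04080_s3 6.30% and 52.0% (adjusted p = 0.000159). The TPM of AT1G04080_s3 did not rise (3.23 in wild type, 2.86 in prp39a). Its share grew because other isoforms were lost, with AT1G04080_P1 at 28.1 and 0.271 TPM. AT1G04080_c2, whose share was not tested, went from 0.792 to 2.35 TPM and from 1.54% to 42.8%. The isoform of LUC7A, a U1-associated protein gene, named AT3G03340_ID1 went from 31.3% to 14.6% in prp39a (adjusted p = 0.00398).

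One hypothesis was that isoform changes of prp39a gather in U1 snRNP and Sm core genes. Of 14 testable genes 7 changed (U1-70K, PRP39A, LUC7A, LUC7B, LUC7RL, SMB-B and SMD1A), where random lists matched on TPM and number of isoforms had a median of 4. Of 10000 such lists 6.3% held as many, and 11% when PRP39A was left out; Fisher's exact test against the other genes, without matching, gave an adjusted p of 0.0299, so the hypothesis stays open. The other was that they gather in trans-acting siRNA genes, the precursors and targets of a pathway that shares its machinery with transgene silencing. Here 4 of 5 genes changed (TAS1A, TAS1C, TAS2 and ARF4), matched lists had a median of 1, and 0.17% held as many. The matched lists were drawn gene by gene, as if genes changed independently. Related genes such as TAS1A and TAS1C may not, because reads shared between similar transcripts are divided, so 0.17% may be too low. The isoform AT2G27400.1 of TAS1A had 42.0% in wild type and 23.0% in prp39a, and AT2G39681.1 of TAS2 had 76.4% and 56.8%. This is consistent with a gathering of changes in this pathway, but rests on 5 genes, on lists tested because of these values, and on TPM of precursors without small RNA data.

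A further hypothesis was that annotated pseudogenes rose more often in smd1b than other changed genes of like TPM. Of 117 tested, 26 changed, 22 higher and 4 lower. Among draws of other changed genes matched on mean TPM the median was 14 higher, and 0.1% of 10000 draws held as many higher. The filter on mean TPM includes smd1b, so a gene low in wild type enters more readily when it rises, and 7 of the 22 had under 1 TPM in wild type. Among changed genes with at least 1 TPM in wild type, matched on that value, 15 pseudogenes rose and 4 fell, and 3.2% of draws held as many higher. With at least 3 TPM in wild type, which passes the filter whatever the mutants have, 7 rose and 4 fell, and 28% of draws held as many, so the hypothesis stays open. The draws were made gene by gene, as if genes changed independently. Pseudogenes may not: AT5G34790, AT5G34800 and AT5G34810 rose by 1.775, 1.821 and 1.798 on the log2 scale. The shares of draws may therefore be too low. In prp39a 7 rose and 2 fell, and the difference between the mutants was not tested. These values do not part release of silenced copies from reads of other copies assigned to them, and neither was tested.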
